A study of Homo sapiens with 8 samples.

How the data were processed

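Gene expression was measured in HuCCT1, an established human cholangiocarcinoma (bile duct cancer) cell line, on 8 Illumina bead arrays. Per the labels, the cells were kept overnight in medium with 1% serum and then given 800 ng/ml of excretory-secretory products (ESP) of the liver fluke Clonorchis sinensis, which are the molecules that adult worms release into buffer. Each array was assigned to its time of exposure by its source name. This gave 1 array at 0 h, 1 at 1 h and 2 each at 3 h, 9 h and 24 h. The free-text description of all 8 samples reads 0 h and was set aside, because the titles and source names give 5 different times. The labels call the second arrays of 3 h, 9 h and 24 h biological replicates without saying how the cultures were separated, so p-values measure only the spread between these samples, part of which may be technical. The deposited columns of the replicate 2 arrays carry ESP in their names and those of the replicate 1 arrays do not. The labels describe all 8 as treated, and the groups follow the labels.

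Per the labels' protocols, total RNA was extracted with TRIzol and biotin-labelled cRNA was made with an Illumina amplification kit. The scanner software and its settings are not given in the sources used here. Each deposited sample file gives the mean signal intensity of a target over its beads on a linear scale, a detection p-value, the count of beads and the standard error over beads, per the file headers. The intensity values were neither background-subtracted nor scaled between arrays, since the lowest signals lay between 71.99 and 79.43 and the medians differed between arrays. The detection p-value deposited for each target compares its signal with the array's own background. A series-wide table of the same arrays holds the authors' log2 values. Its columns have medians of 7.684 to 7.688, each column correlates best with the sample file of its own array, and log2 signals quantile-normalised here differed from it by at most 0.0243. It is therefore on a log2 scale, quantile-normalised and without a background step, while the software used is not given in the sources used here. It held 0 columns without a sample.

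Targets are identified by Illumina target numbers. Of the 20589 numbers, 0 occur in the gene reference table used here, and the files do not pair them with gene names. The 33 gene lists fixed beforehand (777 genes, among them the minichromosome maintenance genes) could therefore not be matched, no list test was run, and a target is not called a gene. The rule for named genes had been to take the largest changes past the threshold whose replicates lay on the same side of the 0 h array. It was applied to target numbers, without its condition on gene symbols, and limited to the 2 highest and 2 lowest at 24 h against 0 h. The beads of a target fix its precision on an array: the median was 40 to 41 beads per target, with at least 10. The number of arrays, not the number of beads, limits every comparison.

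Signals were background-corrected and normalised with limma 3.58.1 in R 4.3.3 (neqc, with negative controls inferred from the detection p-values, an offset of 16, quantile normalisation and log2). A target was kept when its detection p-value was under 0.01 on every array of at least 1 time, which left 9628 targets. A linear model with 1 coefficient per time was fitted to all 8 arrays, followed by limma's moderated test with an intensity trend (eBayes, residual degrees of freedom 3, prior degrees of freedom 4.34). The spread therefore comes from the 3 pairs of arrays, and the single 0 h and 1 h arrays are assumed to vary like them. Contrasts were 1 h, 3 h, 9 h and 24 h against 0 h, and 9 h and 24 h against the earlier replicated times. An F test covered the 5 times, and a slope on log2(hours + 1) was fitted with 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 9628 targets, and a target is called when its value is under 0.05. These settings, the comparisons and the alternatives were fixed before the data were examined, except where stated. Changes repeated in both replicate numbers, at 1.5-fold or more, were counted as a measure added after seeing the data. Its chance value is the product of the counts of each replicate number divided by the targets, which takes every target as equally likely to pass the limit.

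The tests were tried on simulated data with the means and spreads of the 9628 targets and 200 changed targets in each of 5 draws. For 24 h against 0 h, 13.1% of 1.5-fold, 71% of 2-fold and 98.8% of 4-fold changes were recovered, with 44 false calls over the 5 draws. For 24 h against 3 h these shares were 34.9%, 86.9% and 100%, with 59 false calls. For the F test they were 15.2%, 79.7% and 100%, with 84 false calls, and for the slope 37%, 87.8% and 99.7%, with 33. With no change simulated between the times compared, 9 h against 3 h gave 3 false calls and 1 h against 0 h gave 6 over the 5 draws. The simulated arrays were independent, with 1 spread per target at all times. In the data, replicates differed by an SD of 0.39 at 3 h, 0.30 at 9 h and 0.19 at 24 h. The replicate differences at 3 h and 9 h also correlated at 0.59. The shares and false calls therefore hold for the simulated setting and may differ for these arrays. Alternatives were another background and scaling, the authors' table, other offsets and filters, replicate blocks, other estimates of the spread, other baselines and time scales, and leaving out each array in turn.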

Results

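The transcriptome of HuCCT1 cells was followed over 24 h of exposure to 800 ng/ml of C. sinensis ESP, in order to find transcripts that differ between 0 h, 1 h, 3 h, 9 h and 24 h. The 8 arrays measured 20589 targets each. Median raw signals lay between 193.4 and 220.9, and between 8931 targets (1 h) and 9704 targets (3 h replicate 2) were detected, which is 43.4% to 47.1% of all targets. The 0 h and 1 h groups held 1 array each and the later groups 2, so every change from 0 h shares 1 baseline array. All 8 arrays are taken as treated, as the labels state, although the deposited column names give ESP for the replicate 2 arrays only. Cells kept for the same times without ESP were not analysed here, so time with ESP and time in low serum run together in each comparison.

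The 0 h and 1 h arrays stood apart from the later arrays, among which the 24 h arrays lay together while those of 3 h and 9 h lay nearest to each other within a replicate number. The 0 h and 1 h arrays were nearest to each other, with a standard deviation (SD) of log2 differences of 0.24 over 9628 targets, and lay 0.40 to 0.63 from the 6 later arrays. The 24 h arrays were each other's nearest array, at 0.19. At 3 h and 9 h, in contrast, the nearest array was the other time of the same replicate number, at 0.25 for replicate 1 and 0.22 for replicate 2. Replicates of 1 time differed by 0.39 at 3 h and 0.30 at 9 h. At least 2-fold differences between replicates occurred for 219 targets at 3 h, 97 at 9 h and 6 at 24 h. The first principal component held 61.4% of the variance and placed 0 h and 1 h at -29.3 and -42.0, 3 h and 9 h of replicate 1 at 1.04 and 5.73, and the other 4 arrays between 15.7 and 16.7. At most 1 of 20589 raw signals was identical between any 2 arrays. Signals of a target's beads varied most on the 3 h replicate 1 array, with a median coefficient of variation of 34.1% against 21.7% to 25.9% on the others.

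**Figure D1:**
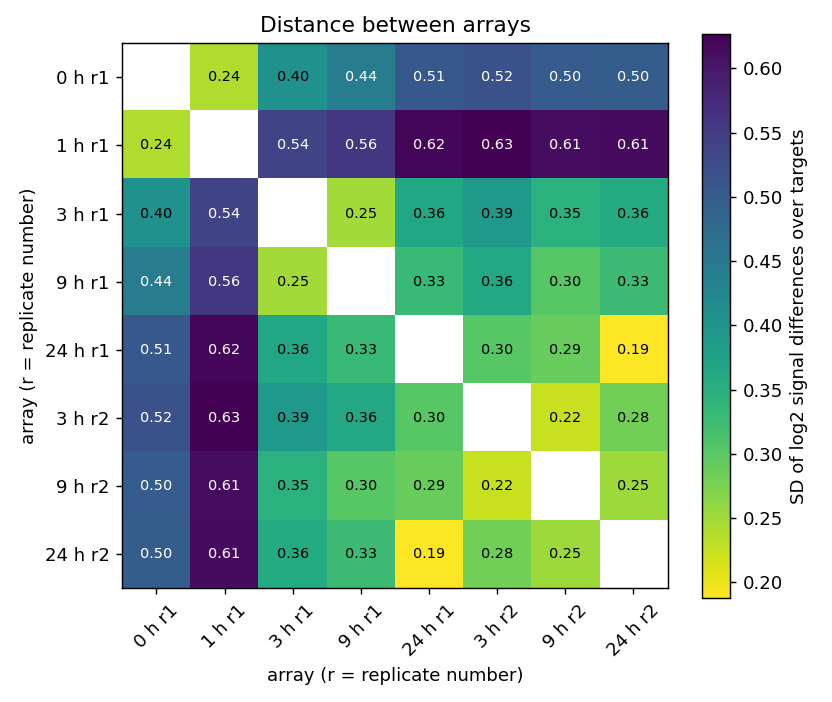
Standard deviation of the log2 signal differences over 9628 targets for each pair of the 8 arrays (both axes: arrays by time and replicate number, r). The 0 h and 1 h arrays lie 0.40 to 0.63 from the later arrays, and the 3 h and 9 h arrays lie nearest to each other within a replicate number.

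A set of targets took a higher level by 3 h and another a lower level. At 3 h against 0 h, 166 of 9628 targets passed limma's moderated test after Benjamini-Hochberg adjustment, of which 135 rose and 31 fell. Their median change was 1.09 on the log2 scale. Of these 166, 113 had changed at least 2-fold. The 135 targets that rose stood at a median of 1.10 on the log2 scale above the 0 h array in both 3 h replicates, and the 31 that fell at -1.02 and -1.09. These levels share the 0 h array with the test that picked the targets. The 135 targets stood at medians of 1.13 and 1.08 at 9 h and at 1.13 on both 24 h arrays. Of the targets that rose, 29 were not detected on the 0 h array, so their size is not measured on that side. The count at 3 h fell to 0 without 24 h replicate 1, 24 h replicate 2 or 9 h replicate 1, to 2 without 9 h replicate 2 and to 46 without 3 h replicate 2, and rose to 728 without 3 h replicate 1. It was 0 with no scaling between arrays or with only the arrays compared, 85 on targets detected on all 8 arrays and 1855 with the mean of the 0 h and 1 h arrays as baseline. Under median scaling 131 rose and 145 fell, so the excess of rises at 3 h depended on the scaling. That scaling moved the median of all targets from -0.03 to -0.13 at 3 h and from -0.03 to -0.10 at 9 h. The 9 h and 24 h arrays enter the comparison of 3 h with 0 h only through the pooled spread, the normalisation and the filter.

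More targets were called at later times, but counts by fold change rose with time in replicate 1 only. At least 2-fold differences from the 0 h array numbered 258, 370 and 512 at 3 h, 9 h and 24 h in replicate 1. In replicate 2 they numbered 554, 499 and 489. The rise in calls is therefore no measure of a response that widened with time. At 9 h against 0 h, 347 targets passed the same test, 255 higher and 92 lower, with a median change of 1.05 on the log2 scale. Of the 255, 60 were not detected at 0 h. The 9 h calls included 125 of the 135 targets that rose at 3 h and 28 of the 31 that fell. Independent lists of these lengths would share 3.58 and 0.296, but all changes from 0 h share the 0 h array, so part of the excess may come from it. Across the 9628 targets, which are not independent replicates, the changes at 3 h and 9 h correlated at r = 0.922, where unchanged targets simulated with a shared 0 h array gave 0.667. Their covariance was 0.173, against 0.0338 simulated. The simulation leaves out the likeness of 3 h and 9 h arrays within a replicate number, which raises both values without any change, so the excess is not an estimate of a shared effect. Without 3 h replicate 1 or 3 h replicate 2 the count was 907 or 941, and without 9 h replicate 1, 9 h replicate 2, 24 h replicate 1 or 24 h replicate 2 it was 1 each time. Median scaling gave 242 higher and 219 lower, the mean of 0 h and 1 h as baseline gave 2092 targets, no scaling 1, only the arrays compared 0 and targets detected on all 8 arrays 165.

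At 24 h against 0 h, 509 targets were called. Of these, 332 rose and 177 fell, and 250 changed at least 2-fold, 175 upward and 75 downward. The median change was 1.00 on the log2 scale, and the smallest called was 0.40. In total 147 targets were called at each of 3 h, 9 h and 24 h, 121 of them higher and 26 lower, and 232 were called at 24 h alone. The changes at 24 h correlated with those at 3 h at r = 0.866 and at 9 h at 0.871, against 0.667 and 0.666 for simulated unchanged targets, with covariances of 0.18 and 0.191 against 0.0338. For these 509 targets, which were picked by their 24 h value, the change at 3 h was a median 83.7% of that at 24 h (quartiles 63.8% and 95%), and at 9 h it was 85.6% (71.4% and 98.3%). Unchanged targets picked in the same number by the smallest p at 24 h, in 20 simulations with the same shared 0 h array, gave medians of 66.1% and 66.5%, so most of such a share can arise without any change. Of the 332 targets, 67 were not detected at 0 h, and of the 177, 14 were detected on neither 24 h array. The count was 1 without 24 h replicate 1 or without 24 h replicate 2, 185 and 209 without 9 h replicate 1 and 2, and 1338 and 1384 without 3 h replicate 1 and 2. With the 0 h and 1 h arrays together as baseline it was 2598, with the 1 h array alone, a baseline added after seeing the data, it was 2097, with no scaling 101 and with only the arrays compared 3905, and median scaling gave 315 higher and 311 lower.

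**Figure D2:**
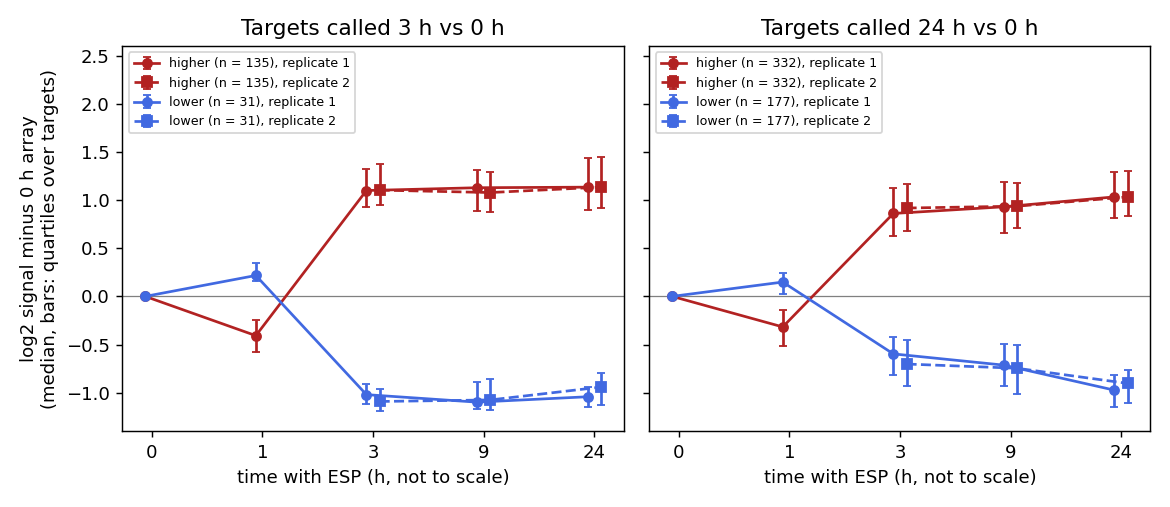
Median log2 signal minus the 0 h array (y axis; bars show the quartiles over targets) against time with ESP (x axis, hours, not to scale), for targets called at 3 h (left) and at 24 h (right), in replicate 1 (circles, solid) and replicate 2 (squares, dashed). The 332 targets that rose by 24 h stand at 0.86 and 0.92 at 3 h and at 1.03 at 24 h, and lie at -0.32 at 1 h.

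By fitted change, the largest called rise was that of target ILMN_2770. Its log2 signal was 8.27 at 0 h, 11.47 ± 1.00 at 3 h (SD, n = 2), 11.29 ± 0.82 at 9 h and 11.89 ± 0.08 at 24 h. This is 12.3-fold at 24 h (log2 change 3.62, standard error 0.60, limma adjusted p = 0.0265). At 3 h its replicates stood at 10.76 and 12.18, and limma's adjusted p was 0.0512. ILMN_26085 rose from 8.55 to 10.82 ± 0.06 (n = 2), or 4.83-fold (limma adjusted p = 0.0148), and had also risen at 3 h and 9 h (adjusted p = 0.0442 and 0.04). ILMN_20932 fell at each of 3 h, 9 h and 24 h against 0 h, and its levels were 12.58 at 0 h, 10.75 ± 0.06 at 3 h, 9.85 ± 0.08 at 9 h and 9.07 ± 0.09 at 24 h (SD, n = 2 each). It was 11.4-fold lower at 24 h (log2 change -3.51, standard error 0.14, limma adjusted p = 0.000239), and its 24 h level was also below its 3 h level (log2 change -1.68, limma adjusted p = 0.0112), a call lost without 9 h replicate 1, without either 24 h array, with no scaling between arrays and with only the arrays compared. ILMN_7069 was at 9.84 at 0 h and was detected on neither 24 h array, which makes it at least 6.59-fold lower at 24 h (limma adjusted p = 0.0154). The bound is the 0 h level over the mean, on both 24 h arrays, of the higher of the target's own signal and the dimmest detected signal. It equals 2.72 on the log2 scale and holds for the main background correction and offset only. The log2 change itself was smaller with no background step (-2.378) and in the authors' table (-2.385). At 3 h it stood at 8.68 ± 0.75 and at 9 h at 8.33 ± 0.50, with adjusted p = 0.194 and 0.104. ILMN_2770, ILMN_26085 and ILMN_7069 lost their calls without 24 h replicate 1 and without 24 h replicate 2, and ILMN_2770 also with no scaling between arrays and with a robust estimate of the spread. Without 24 h replicate 1 and 2 in turn, the log2 changes were 3.56 and 3.68 for ILMN_2770 and 2.32 and 2.23 for ILMN_26085. Over all 23 alternatives they ran from 3.2 to 4.594 for ILMN_2770 and from 1.973 to 3.125 for ILMN_26085. The lowest came from the authors' table and the highest from the 1 h array as baseline.

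**Figure D3:**
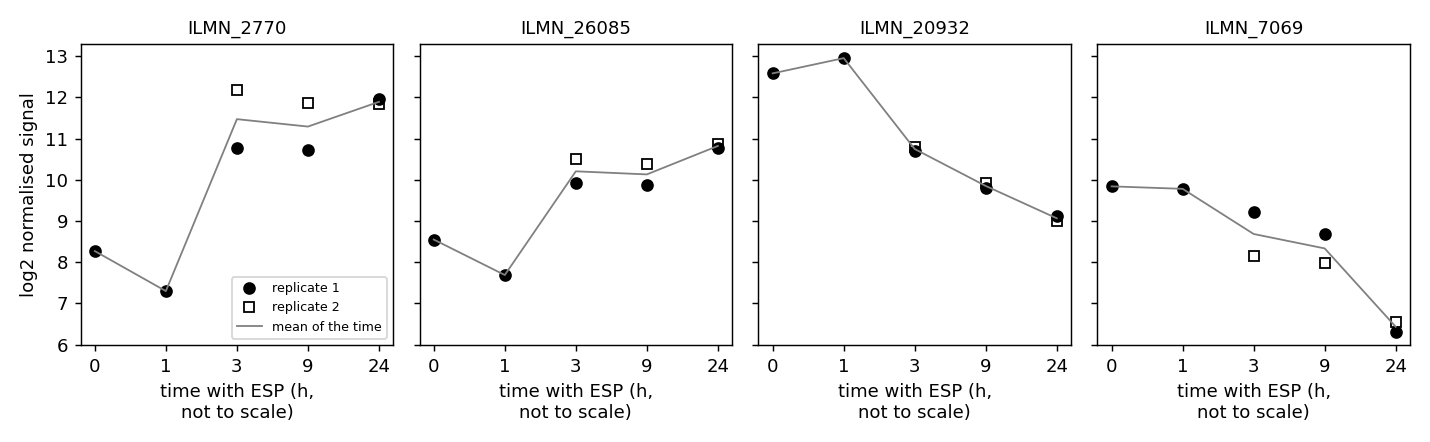
Normalised log2 signal (y axis) of 2 targets called higher and 2 called lower at 24 h against 0 h, chosen by the size of the fitted change, which is only bounded for ILMN_7069, by time with ESP (x axis, hours, not to scale). Filled circles are replicate 1, open squares replicate 2 and the line the mean of each time; ILMN_20932 falls from 12.58 to 9.07 with replicates close together, while the replicates of ILMN_2770 stand apart at 3 h and 9 h.

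Some targets were detected only on the early or only on the later arrays. Totals differed little, with 9002 and 8931 targets detected at 0 h and 1 h and 8993 to 9704 on the later arrays. How many targets would cross the detection limit in this way without any change was not estimated. A group of 161 targets was detected on neither the 0 h nor the 1 h array and on all 6 later arrays, and 38 showed the reverse. The first group held 55 targets called at 24 h against 0 h and the second 1. The direction in each group follows from how it was picked, and sizes are not given because 1 side was not above background.

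At 1 h against 0 h no target was called. With 1 array per time and the spread taken from the later pairs, limma gave 0 of 9628 targets at an adjusted p under 0.05 and 300 at an unadjusted p under 0.05. The 300 are less than a 0.05 share of the 9628 targets, so they are no sign of change. At least 2-fold differences were seen for 6 higher and 19 lower targets. The targets called at later times lay on the other side of 0 h at this time. Of the 332 that rose by 24 h, 296 were below their 0 h level at 1 h, with a median of -0.32, and of the 177 that fell, 136 were above it, with a median of 0.15. Across all 9628 targets, which are not independent replicates, the change at 1 h correlated with that at 24 h at r = -0.299. Unchanged targets simulated with the same shared 0 h array gave r = 0.577. The covariance was -0.0355, against 0.0337 simulated.

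Changes among the later times rest on 2 arrays on each side. Between 3 h and 24 h, 7 targets were called by limma's moderated test, 3 of them higher and 4 lower at 24 h. Of the 3 higher targets, 1 was detected on neither 3 h array, so the size of its rise was not measured. Target ILMN_20932 had the largest of the 4 falls, all of which were detected at both times. Without 3 h replicate 1 the count was 13, without 9 h replicate 2 it was 1, and without 9 h replicate 1 or either 24 h array it was 0. It was also 0 with no scaling or only the arrays compared, 3 without the intensity trend and 4 under median scaling. Between 3 h and 9 h and between 9 h and 24 h, 0 targets were called, with 272 and 709 at an unadjusted p under 0.05 and smallest adjusted p of 0.429 and 0.133. Of the 9628 targets, the 272 are less than a 0.05 share and the 709 more. With the replicate number as a block, 0 were called between 3 h and 9 h, 35 between 9 h and 24 h and 29 between 3 h and 24 h. The 0 calls without a block are therefore no evidence that nothing changed between 9 h and 24 h. Without 3 h replicate 1, without 3 h replicate 2, or with only the arrays compared, 7 were called between 9 h and 24 h.

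Changes between later times were partly repeated when each replicate number was taken on its own, a comparison that shares no array. From 9 h to 24 h, 55 targets were higher and 53 lower by at least 1.5-fold in both replicate numbers, where independent lists would share 5.33 and 4.49, and 7 went in opposite directions. From 3 h to 24 h these numbers were 28 and 53, against 6.9 and 8.92, with 26 opposite. From 3 h to 9 h they were 13 and 16, against 1.22 and 2.03, with 7 opposite. Across the 9628 targets the changes of replicate 1 and 2 correlated at r = 0.387 from 9 h to 24 h, at 0.156 from 3 h to 24 h and at 0.0726 from 3 h to 9 h. In both replicate numbers 17 targets were lowest at 24 h, by at least 1.5-fold from both 3 h and 9 h, where 1.04 would be shared by independent lists. Another 5 were highest at 24 h (0.923), 5 highest at 3 h (0.297), 2 lowest at 3 h (0.151), 6 highest at 9 h (0.0663) and 5 lowest at 9 h (0.109). These counts are of fold changes without a test per target, and with no background step the totals were 9 from 3 h to 9 h, 54 from 9 h to 24 h and 43 from 3 h to 24 h. The measure was chosen after seeing the data. The values for independent lists take every target as equally likely to pass 1.5-fold, and none is given for the opposite counts. If some targets vary more than others, unchanged targets would also share more than these values. The excess over them is therefore not an estimate of repeated change.

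**Figure D4:**
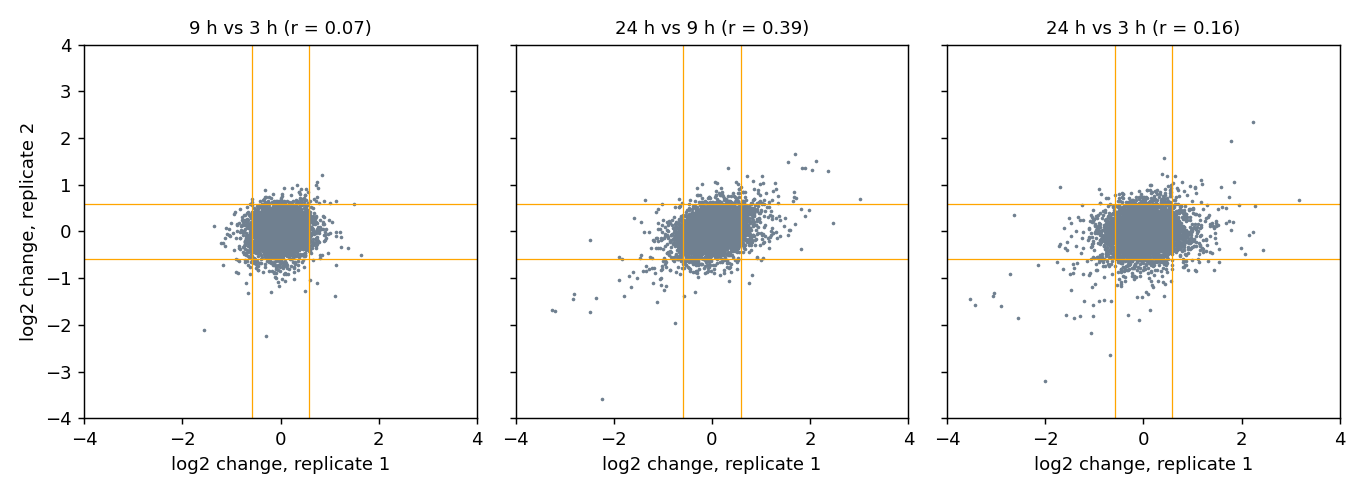
Log2 change of each of 9628 targets in replicate 1 (x axis) and replicate 2 (y axis) for 9 h against 3 h, 24 h against 9 h and 24 h against 3 h. Orange lines mark 1.5-fold; the correlation across targets is 0.07, 0.39 and 0.16.

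Over the whole course, 965 of 9628 targets differed among the 5 times by limma's F test at an adjusted p under 0.05, and 548 of the 592 targets called at 3 h, 9 h or 24 h against 0 h were among them. In the simulated data the false share of the F-test calls was above 0.05. ILMN_20932 had an F-test adjusted p of 0.000409. A slope on log2(hours + 1) was called for 188 targets, 76 rising and 112 falling, of which 143 were also called at 24 h against 0 h. The shape of the course was not tested, so a step followed by a level course can also give such a slope. ILMN_20932 fell by 0.85 on the log2 scale per unit of log2(hours + 1), with a standard error of 0.09 (limma adjusted p = 0.00572). Within the 5 replicate 1 arrays alone 31 slopes were called, and within the 3 replicate 2 arrays 28. The slope count depended on the time scale, with 6 on hours and 944 on the rank of the time, and was 112 with no scaling, 333 under median scaling and 105 without the intensity trend. The F-test count was 422 with no scaling, 41 and 46 without 24 h replicate 1 and 2, 431 and 416 without 9 h replicate 1 and 2, and 1913 and 1816 without 3 h replicate 1 and 2. The slope count was 1 without 0 h, 29 without 1 h, 2021 without 3 h replicate 2, 55 and 16 without 9 h replicate 1 and 2, and 0 and 2 without 24 h replicate 1 and 2.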

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

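The change from 0 h differed between 3 h and 24 h for 7 of 9628 targets by limma's test of 24 h against 3 h (adjusted p from 0.0112 to 0.0445). For 6 of these 7 targets the fitted changes from 0 h at the 2 times did not point the same way, mostly because the change at 3 h was near 0, and 1 of the 6 was detected on neither the 0 h array nor the 3 h arrays. The exception was ILMN_20932, which fell by 1.83 on the log2 scale by 3 h and stood at a further -1.68 at 24 h against 3 h. The count of 7 became 13 without 3 h replicate 1, 1 without 9 h replicate 2, and 0 without 9 h replicate 1, 24 h replicate 1 or 24 h replicate 2, and the fall of ILMN_20932 from 3 h to 24 h was among the calls lost in the last 3. The count was also 0, and this call lost, with no scaling between arrays and with only the arrays compared. No group held 4 or more arrays, so single arrays were not tested as outliers.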

How the results depend on the processing

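Chosen after the data were seen were cyclic loess, the 1 h array alone as baseline, leaving out the 1 h array for changes from 0 h, the later arrays alone, slopes within a replicate number, and the repeated changes with their fold limits. The counts of called targets depended strongly on which arrays entered the fit, on the baseline and on the scaling. The 4 named targets kept their direction under every alternative in which they were tested (23 each, 22 for ILMN_7069). ILMN_20932 stayed past the threshold in all 23, ILMN_26085 in 21 of 23, ILMN_7069 in 20 of 22 and ILMN_2770 in 19 of 23. Of 241 alternative counts, 148 lay within 1.5 times the main count, 33 above and 60 below. A count of 0 against a main count of 0 was taken as within. The main count was 0 for 1 h against 0 h, 9 h against 3 h and 24 h against 9 h. Every alternative for 1 h against 0 h and for 9 h against 3 h gave 0 as well, so the 148 overstate how stable the other counts were. Leaving out 1 array at a time gave 41 to 1913 targets for the 5 times, 0 to 728 at 3 h, 1 to 941 at 9 h and 1 to 1384 at 24 h against 0 h, 0 to 7 for 24 h against 9 h, 0 to 13 for 24 h against 3 h and 0 to 2021 for the slope. An arm left with 1 array was assumed to vary like the other times. With the replicate number as a block (replicate block), the counts were 384, 546 and 875 at 3 h, 9 h and 24 h against 0 h, 35 for 24 h against 9 h, 29 for 24 h against 3 h and 26 for the slope. As a random block it gave 442, 655 and 968 against 0 h, but 0, 7 and 189 for the other 3, close to or at the counts without a block. The numbers were left out of the main fit because the labels do not say that they mark a shared culture or day. In the data, the deviations of same-numbered arrays correlated at 0.59 for 3 h and 9 h, 0.16 for 9 h and 24 h and only 0.051 for 3 h and 24 h. The main fit treats the 3 h and 9 h arrays of a replicate number as independent, which the 0.59 goes against. The mean of 0 h and 1 h as baseline gave 1855, 2092 and 2598 targets at 3 h, 9 h and 24 h, and the 1 h array alone 1469, 1626 and 2097. Only the arrays compared gave 0 at 3 h, 0 at 9 h and 3905 at 24 h against 0 h, 7 for 24 h against 9 h and 0 for 24 h against 3 h. With no scaling between arrays the counts were 422 for the 5 times, 0, 1 and 101 at 3 h, 9 h and 24 h against 0 h, 0 for 24 h against 3 h and 112 for the slope. Median scaling gave 276 at 3 h, 4 for 24 h against 3 h and 333 for the slope. Without the intensity trend 24 h against 3 h gave 3 and the slope 105. Targets detected on all 8 arrays gave 85 at 3 h and 165 at 9 h, where 8248 targets enter. Requiring 2-fold left 197 at 9 h and 250 at 24 h. The slope gave 6 in hours, 944 on the rank of the time, and 31 and 28 within replicate 1 and 2. Changes of 1.5-fold repeated from 3 h to 9 h, 9 h to 24 h and 3 h to 24 h numbered 9, 54 and 43 both with no background step and in the authors' table, 13 and 71 for the first 2 with an offset of 64, 14 and 68 on targets detected on all arrays, 221, 531 and 437 at a lower fold limit and 1, 24 and 22 at 2-fold. Stricter fold limits and filters leave fewer targets by construction. Leaving out an array of a pair also takes that pair out of the pooled spread. Replicates differed by an SD of 0.389 at 3 h, 0.302 at 9 h and 0.188 at 24 h. The pooled spread is therefore wider without a 24 h array and narrower without a 3 h array. For 24 h against 0 h with only the arrays compared, it rests on the 24 h pair alone. Other causes of these shifts were not tested. Tests of the gene lists were not run, and 1 h against 0 h has no fit on its own arrays, since it leaves no residual degrees of freedom. Signal near background limits the sizes: 67 of the 332 targets that rose at 24 h were not detected at 0 h.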

Other observations

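The tests below were chosen after the patterns had been seen, except that of a faster course in replicate 2.

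Targets called at 24 h lay on the opposite side of 0 h at 1 h. Noise of the single 0 h array that is unrelated to the course would make the 2 changes correlate positively (0.577 simulated), whereas r was -0.299. A signal-dependent scaling difference of the 1 h array was tested within 6 bands of mean signal: in the 5 upper bands r was at most -0.353, which argues against it there, while in the lowest sixth r was -0.0768 and such a difference stays open. A shift of the 0 h array along the course would give a negative r too and was not tested. With 1 array at each of 0 h and 1 h, a fault of either array or its RNA cannot be told apart from an early dip of the cells before the later change. A second array at both times would be needed.

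The 3 h and 9 h arrays resembled each other more within a replicate number than within a time. A constant offset between the replicate numbers would also appear at 24 h, but the replicate differences at 24 h correlated at only 0.0513 with those at 3 h and 0.16 with those at 9 h. A swap of the labels of 9 h replicate 1 and 3 h replicate 2 stays open. Of the few targets that differed 1.5-fold from 3 h to 9 h in both replicate numbers, 80.6% went the same way (29 against 7, exact 95% binomial interval 64% to 91.8%). A swap would give even shares only if the replicate differences at 3 h and 9 h were unrelated, so this share does not decide. ILMN_20932 stood at 10.70 and 10.79 at 3 h and at 9.79 and 9.91 at 9 h, but 1 target decides nothing for the set. Targets are not independent, and r over all 9628 was only 0.0726. Across the replicate numbers, 9 h replicate 2 minus 3 h replicate 1 correlated at -0.522 with 9 h replicate 1 minus 3 h replicate 2. A swap would give a negative value, but the likeness within a replicate number gives one too, so this value does not decide either. An offset of the 3 h and 9 h arrays of replicate 1 that is unrelated to the course would not go with the change from 0 h to 24 h, but the 3 h replicate difference correlated with it at 0.37. As a hypothesis, replicate 2 may have run a faster course. Its lead at 3 h correlated at 0.426 with the later change of replicate 1 from 9 h to 24 h, which shares no array with it. However, the 3 h and 9 h arrays of replicate 1 are both subtracted, so any offset common to them gives a positive value. The 0.426 therefore does not favour a faster course. The label swap, an offset common to these 2 arrays that runs along the course, or a technical property that also sets 0 h and 1 h apart would give a positive value too. Each of these stays open, as does a difference in how the replicate 1 cultures were treated.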
